A study of Callithrix jacchus with 3 samples.

How the data were processed

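Testis small RNA, RNA recovered with MARWI and testis RNA of the common marmoset were measured by sequencing. Per the labels' protocols, total small RNA was gel-purified by size from RNA extracted with the miRNeasy kit, MARWI was immunoprecipitated from testis lysate and its RNA extracted with the same kit, and both kinds of small RNA library were made with the NEBNext small RNA reagents. RNA-seq libraries were made from total RNA with a directional mRNA protocol and a TruSeq small RNA kit, per the labels. The submitters' processing notes name Bowtie, TopHat and Cufflinks without versions or roles. Read trimming, filters, mapping settings and the genome build are not given in the sources used here. Coordinates are printed as the deposited RNA-seq table gives them.

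The small RNA tables, as deposited, give whole-number read counts per distinct sequence, with no normalization and no genome position. The total library lists 20 to 51 nt and MARWI-IP lists 24 to 33 nt, so a length filter preceded deposit of the latter, and its sum is not the depth of that library. Per the labels, MARWI-IP and RNA-seq had 2 replicates from animals aged 41 and 51 months, and the deposited tables hold 1 column for each. The deposited RNA-seq values are RPKM per transcript, above 0 only, with no counts, so the depth behind them is unknown. With 1 column per group no spread between samples, no p-value and no comparison of ages could be computed.

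Shares of reads were computed over 24 to 33 nt, the range both tables hold. The plan named reads of the library, and this range replaced it once the lengths had been seen, with all reads of the total library as an added alternative. The window called piRNA-length was 26 to 32 nt. Each share has an exact (Clopper-Pearson) 95% interval. The ratio of a small RNA's share in MARWI-IP to that in total small RNA has an exact interval from the binomial of its read counts. Where MARWI-IP had 0 reads, the limit of 3 reads was used. Reads were assigned to 45 miRNAs, 6 tRNA 5′ parts, 2 Y RNAs and 2 rRNAs by their first 18 nt. These sequences were written from knowledge of mammalian, mainly human, RNAs before the data were examined, so reads that differ from them within the first 18 nt were missed. The tRNA-Glu-TTC fragments were added afterwards, and 1 further listed tRNA part is not used here. The planned share of tRNA fragment reads, which needs all listed parts, is therefore not given, and 1 of the 5 most abundant MARWI-IP sequences is not named. The alternative without listed miRNA and tRNA reads leaves out the 6 parts alone.

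Complementary 5′ ends were counted from sequence. For each length of 1 to 21 nt, the weight of read pairs whose first bases were reverse complements was divided by that expected from the base shares at each position, with palindromes left out. The planned score sets the ratio at 10 nt against those at the other overlaps of 1 to 20 nt, as a difference from their mean in SDs, and it is the score reported first. The plan did not fix the scale of the ratio, and the plain ratio was used. It is governed by ratios that rise with overlap length. A score on the log2 scale, and a score of the log2 ratio at 10 nt relative to the mean of its neighbours, set against the same quantity at the other 18 overlaps, are alternatives chosen on these data, after exploratory counts had shown the peak at 10 nt. The counting was tested on simulated reads with planted pairs. Because the pairs are not placed on a genome, repeats and chance matches between loci count among them.

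Entries of the RNA-seq table were named from the table's own names. Names of the form LOC with a number were turned into symbols through the RefSeq gene table of assembly calJac240_pri, used for names alone, which matched 6593 transcripts and left 506 unmatched. Another 48 were named through the Ensembl gene table and 2330 had no name. Entries of 1 symbol were summed. The 14 gene lists, with 148 entries, were fixed before the data were examined, and a list's median was ranked among 10000 random lists of as many named protein-coding genes. The ranking was tested on simulated lists.

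Named items followed a rule fixed before the data were examined: the 4 highest members of each list and those under 1 RPKM, the 10 highest RNA-seq entries, the 15 most abundant listed miRNAs, the highest and lowest miRNA ratio, tRNA fragments with 100 reads and the 5 most abundant piRNA-length sequences of each library. Further members, sequence pairs, Y RNAs, miR-15a-5p and the highest protein-coding genes were named after their values were seen.

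Alternatives were other length windows (24 to 33 and 28 to 31 nt), counting distinct sequences, leaving out sequences read once, the 10 most abundant sequences or listed miRNA and tRNA reads, other matching rules for miRNAs, and detection limits of 0.1 and 5 RPKM. No genome of the build behind the tables was at hand, so piRNA clusters, annotation of reads, antisense and sense reads per gene and overlaps from genome positions were not analysed here. Comparisons between replicates were not made because each dataset is 1 column. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.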

Results

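Small RNAs and gene expression were profiled in the adult testis of the common marmoset (Callithrix jacchus), a New World monkey. MARWI is the marmoset counterpart of the mouse PIWI protein MIWI, and PIWI proteins of the testis bind piRNAs, a class of small RNAs longer than microRNAs (miRNAs). The series held 3 datasets: total small RNA from an animal aged 41 months, small RNA recovered by immunoprecipitation of MARWI (MARWI-IP), and RNA-seq of testis RNA. The labels give MARWI-IP and RNA-seq 2 replicates each, from animals aged 41 and 51 months, and each of these datasets was deposited as 1 column of values. No value below therefore has a replicate error, and no test between datasets was made. The total library held 14138166 reads of 20 to 51 nt. The MARWI-IP table held 110209593 reads of 6912324 distinct sequences and listed lengths of 24 to 33 nt alone, so its sum is that of a length class. The 2 libraries were compared over 24 to 33 nt, where the total library held 12792323 reads. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only, since the reads carry no molecular identifiers.

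The first question was which lengths of small RNA the testis contained and which were recovered with MARWI. Testis small RNA was dominated by RNAs of 29 and 30 nt, and these lengths made up a larger part of the MARWI-IP library. Reads of 29 nt were 27.5% and reads of 30 nt 26.7% of the total library between 24 and 33 nt, against 33.7% and 32.1% of MARWI-IP. Together they were 54.2% of total reads and 65.8% of MARWI-IP reads. Reads of 31 to 33 nt went the other way, at 18.6% of total and 11.9% of MARWI-IP reads.

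The window of 26 to 32 nt, called piRNA-length here, held 93.8% of total reads and 96.7% of MARWI-IP reads of 24 to 33 nt. These intervals were narrower than the last digit printed. Over all lengths of the total library, piRNA-length reads were 84.9% and reads of 21 to 23 nt, the length of miRNAs, were 7.26%. Among 5′ ends (identical first 20 nt) with 100 or more reads, the commonest sequence was 29 nt long at 37.6% and 30 nt long at 36.4% of 72948 ends in MARWI-IP, and it was 29 nt long at 35.6% of 15535 ends in the total library. The commonest sequence held a median of 55.0% of the reads of its end in MARWI-IP and 56.4% in the total library. The total library was size-selected on a gel and came from 1 animal, whereas the labels give MARWI-IP replicates from 2 animals. The libraries thus differed in more than the immunoprecipitation.

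**Figure D1:**
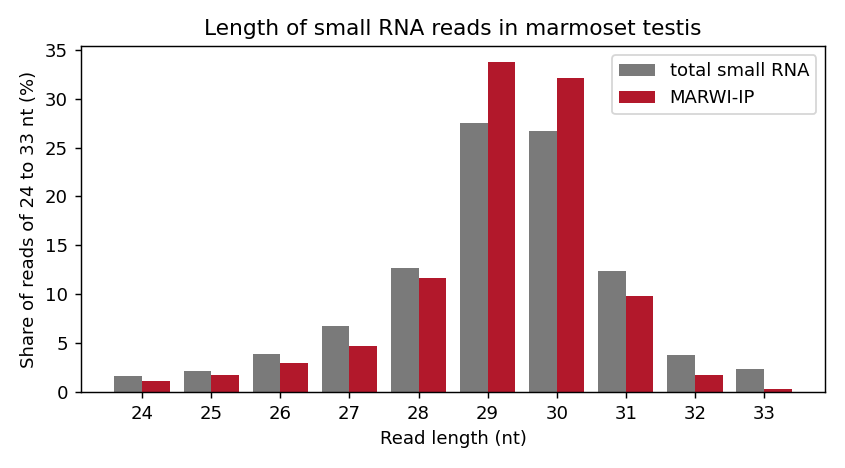
Length of small RNA reads as a share of reads of 24 to 33 nt in total small RNA (grey) and MARWI-IP (red), 1 library each. Reads of 29 nt were 27.5% of the total and 33.7% of the MARWI-IP library.

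The next question was whether these reads carried the sequence features known for piRNAs, a uridine (U) as first base and, for piRNAs made by reciprocal cleavage of complementary transcripts (the ping-pong cycle), an A at position 10. Most piRNA-length reads began with U in both libraries, 84.0% in total small RNA and 89.9% in MARWI-IP. G was the first base of 6.24% of total and 2.37% of MARWI-IP reads. An A at position 10 was found in 30.6% of total and 32.2% of MARWI-IP reads. An A at position 5 was more frequent than at position 10, at 37.3% of total and 44.0% of MARWI-IP reads, and G at position 5 fell to 10.4% in MARWI-IP.

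The first base depended on abundance. In MARWI-IP, U was first in 70.8% of the sequences read once and in 93.9% of those with over 1000 reads, and in the total library it rose from 73.3% of sequences read once to 92.4% of those with over 100 and up to 1000 reads and was 86.7% of those with over 1000. When each distinct piRNA-length sequence was counted once, the order of the libraries turned, with 75.5% in the total and 72.8% in the deeper MARWI-IP library. After MARWI-IP was thinned at random to the 12792323 reads of the total library, a step chosen after seeing the data, 76.1% of its distinct sequences began with U.

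Across positions 5 to 15 other than 10, the share of A averaged 26.6% in total and 28.8% in MARWI-IP reads, with position 5 the highest in both. Without position 5, which was left out of the comparison after seeing the data, the mean was 25.4% (23.03% to 29.3%) in total and 27.1% (24.8% to 31.5%) in MARWI-IP reads, so position 10 lay above the rest by a small margin. Reads that did not begin with U had an A at position 10 more often than reads that did, 38.3% against 31.5% in MARWI-IP and 34.1% against 29.96% in the total library. In the total reads without a first U, A was more frequent still at position 14, at 43.1%. These 1922758 reads include the tRNA-Gly-GCC fragment, which has G at position 10 and A at position 14. It had 181179 reads at 31 nt and 88245 at 32 nt. The shares without it were not computed, so those of the total reads without a first U are not shares of piRNAs alone. Over distinct sequences of this kind position 14 did not lead, and the highest of positions 5 to 15 other than 10 was position 5, at 32.4%. Counted over distinct sequences, 41.9% of total sequences without a first U had an A at position 10, against 29.1% of those with one.

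**Figure D2:**
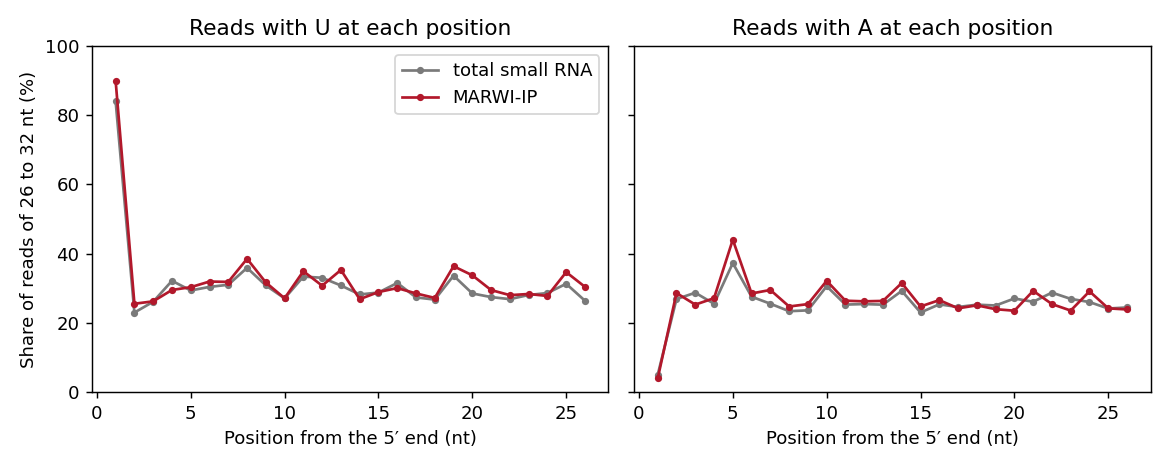
Share of piRNA-length reads with U (left) and A (right) at each of the first 26 positions, in total small RNA (grey) and MARWI-IP (red). U peaks at position 1, at 84.0% and 89.9%, and A peaks at position 5, at 37.3% and 44.0%.

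Complementary 5′ ends were then sought from the sequences alone, because ping-pong partners overlap by 10 nt at their 5′ ends. The planned score sets the 10-nt overlap against all other overlaps of 1 to 20 nt, and z was -0.0903 in MARWI-IP and -0.323 in total small RNA. The mean observed to expected ratio of those other overlaps was 52.5 and 1586, set by the longest ones. This score therefore cannot decide whether pairs over 10 nt are in excess. Against the adjacent overlaps of 9 and 11 nt, a comparison chosen after seeing the data, pairs over 10 nt were more frequent in both libraries, and a few abundant sequences carried most of them. The leading partners in MARWI-IP were reads starting TTGATGGTAATTGGAAGAGC, with 1077345 reads, and reads starting TTACCATCAACATAGAAACT, with 285478 reads. The next were TTCTTTAGTAGCACGTCTGG, with 462137 reads, and TACTAAAGAACTTGCTCATG, with 253150 reads. In the total library the leading partners were TCTTCATTGAGTCTGAAGAC, with 63464 reads, and TCAATGAAGACGACCCCCAA, with 7035 reads.

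Read pairs complementary over the first 10 nt were 39.2 times as frequent in MARWI-IP, and 15.03 times in the total library, as the base shares at each position predict. The ratio was 1.29 and 1.38 at 9 nt and 2.16 and 2.66 at 11 nt. It rose again with longer overlaps, to 14.4 and 21.1 at 13 nt and to 633 and 20524 at 20 nt, and 4 other overlaps in MARWI-IP and 7 in the total library lay above the 10-nt value. This rise is why the planned score is near 0. A score of each overlap relative to the mean of its neighbours, which takes out that rise and was chosen after seeing the data, was 4.74 in MARWI-IP and 4.28 in the total library. Both scores describe a library and are not tests of samples. The leading pair made up 65.0% of the 10-nt pairs of MARWI-IP, and with the 5 leading pairs left out, also chosen after seeing the data, the ratio at 10 nt was 2.39 in MARWI-IP and 3.82 in the total library. With each distinct sequence counted once, the ratio at 10 nt was 1.70 and 2.14, between those at 9 and 11 nt. Among the 2000 most abundant 5′ ends, each counted once, 15 pairs were complementary over 10 nt in MARWI-IP where 4.43 were expected, and 22 in the total library where 3.21 were expected. At 9 nt the counts were 15 where 11.9 were expected and 9 where 8.36 were expected, and at 11 nt 2 where 0.869 were expected and 2 where 0.568 were expected. Ends in the 10-nt pairs among those 2000 held 3.38% and 3.51% of piRNA-length reads. Among the 10000 most abundant ends the ratio at 10 nt was 1.96 in MARWI-IP, no higher than the 1.97 at 11 nt, and 2.78 in the total library against 2.14 at 11 nt.

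**Figure D3:**
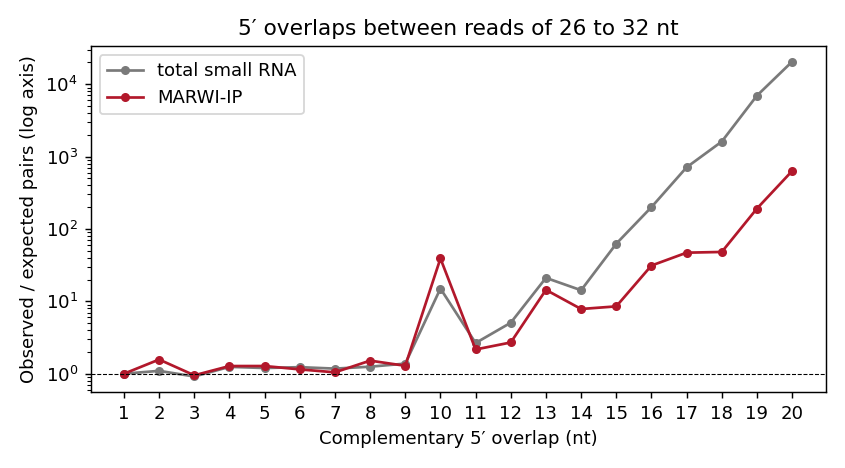
Observed over expected frequency of read pairs whose first n bases are reverse complements, for overlaps of 1 to 20 nt, on a log axis, in total small RNA (grey) and MARWI-IP (red). The ratio at 10 nt was 15.03 and 39.2, against 1.38 and 1.29 at 9 nt, and it rose to 20524 and 633 at 20 nt.

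Known small RNA classes were compared next. The listed miRNAs of the testis were led by miR-34c-5p, and the few of their reads that were 24 nt or longer had a lower share in MARWI-IP. Reads under 24 nt, the length of most listed mature miRNAs, are not in the MARWI-IP table, so most miRNA reads could not be compared. tRNA 5′ fragments differed by tRNA and by length. The fragment of tRNA-Gly-GCC, the most abundant in total small RNA, was 112-fold lower in MARWI-IP. Those of tRNA-Glu-TTC, added after seeing the data, were enriched over 24 to 33 nt and included the most abundant sequence of the MARWI-IP library. Over this range, all fragments used here that start with G were lower in MARWI-IP. Those starting with U were tRNA-Asp-GTC, at a ratio of 0.781, and tRNA-Glu-TTC, above 1. Differences between these tRNAs therefore cannot be told apart from differences by first base.

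Of 45 listed miRNAs, 38 had 100 or more reads in the total library and 3 had none, and together they made up 3.003% of its reads of all lengths. miR-34c-5p, known from meiotic and later germ cells, had 85106 reads. It was followed by miR-21-5p with 35258, miR-99a-5p with 28119, miR-449a, of the same seed family as miR-34c, with 22924, miR-26a-5p with 22380 and miR-191-5p with 21702 reads. The next were miR-100-5p with 18029, miR-20a-5p with 16157, miR-143-3p with 15969, miR-103a-3p with 13831 and miR-125b-5p with 12708 reads. The last of the 15 most abundant were let-7a-5p with 12215, miR-22-3p with 11947, miR-92a-3p with 10475 and let-7f-5p with 9633 reads.

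Of 424542 listed miRNA reads in the total library, 21945 were of 24 to 33 nt. In this range, listed miRNA reads were 0.172% of the total library (0.169% to 0.174%) and 0.00380% of MARWI-IP (0.00369% to 0.00392%), a share 45.1-fold lower. Over distinct sequences the shares were 0.00471% and 0.00187%, a smaller difference, and miR-449a and miR-15a-5p made up 59.3% of the MARWI-IP miRNA reads. All 16 miRNAs with 100 or more total reads in this range had a lower share in MARWI-IP, and 14 had under 0.1 times their total share. miR-451a had 174 reads in the total library and 0 of 110209593 in MARWI-IP, so its share was at least 500-fold lower, taking 3 reads as the limit that a count of 0 allows. Among these 16 miRNAs, the highest ratio belonged to miR-449a, at 0.599 (0.534 to 0.674). Its commonest MARWI-IP reads of this range ran past the mature 3′ end, as in TGGCAGTGTATTGTTAGCTGGTTGAATATG of 30 nt, with 489 MARWI-IP and 97 total reads. miR-15a-5p had a ratio of 0.538 (0.450 to 0.647), also from reads such as TAGCAGCACATAATGGTTTGTGGATTTTG of 29 nt.

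Listed tRNA 5′ fragments were compared one by one between 24 and 33 nt. With 1 listed fragment not used here, no share of all tRNA fragments is given. tRNA-Gly-GCC had 487589 total reads, 3.81% of the library, and 37360 MARWI-IP reads, 0.0339%, a ratio of 0.00889 (0.00880 to 0.00899). Its log2 ratio of -6.81 was -2.68 with the 10 most abundant sequences of each library left out and -4.48 with those of either left out of both. Within single lengths its ratio ran from 0.390 at 26 nt and 0.213 at 27 nt to 0.00904 at 31 nt. Its commonest form in both was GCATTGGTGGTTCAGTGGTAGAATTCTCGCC. tRNA-Lys-CTT was 390-fold lower in MARWI-IP, tRNA-Gly-CCC 113-fold, tRNA-Val-CAC 11.1-fold, tRNA-His-GTG 8.05-fold and tRNA-Asp-GTC 1.28-fold. Of the tRNA-Glu-TTC fragments, the one starting TCCCACATGGTCTAGCGGTTAGGATTCCT had a ratio of 5.32 (5.28 to 5.37) and the one starting TCCCATATGGTCTAGCGGTTAGGATTCCT a ratio of 6.09 (6.01 to 6.17). Together they made up 0.636% of total and 3.53% of MARWI-IP reads. With the 10 most abundant sequences of each library left out, their log2 ratios of 2.41 and 2.61 were 2.16 and 0.37, and 2.15 and 2.31 with those of either left out of both. Within single lengths, a comparison chosen after seeing the data, the more abundant one had a ratio of 4.55 at 29 nt and 5.83 at 30 nt but 0.198 at 31 nt and 0.0477 at 32 nt, and the less abundant one had 5.99 at 30 nt, 0.0852 at 32 nt and 2.05 at 33 nt. tRNA-Val-CAC likewise had 1.28 at 28 nt and 0.00831 at 32 nt, and tRNA-His-GTG 0.775 at 29 nt and 0.00642 at 31 nt. tRNA-Asp-GTC lay on both sides of 1, with 3.24 at 28 nt, 0.536 at 29 nt, 1.41 at 31 nt and 0.913 at 32 nt. Fragments of Y RNAs, small RNAs of the Ro ribonucleoprotein, were lower in MARWI-IP by 62.6-fold for Y-RNA-4 and 209-fold for Y-RNA-1, and those of 5S rRNA by 26.2-fold.

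**Figure D4:**
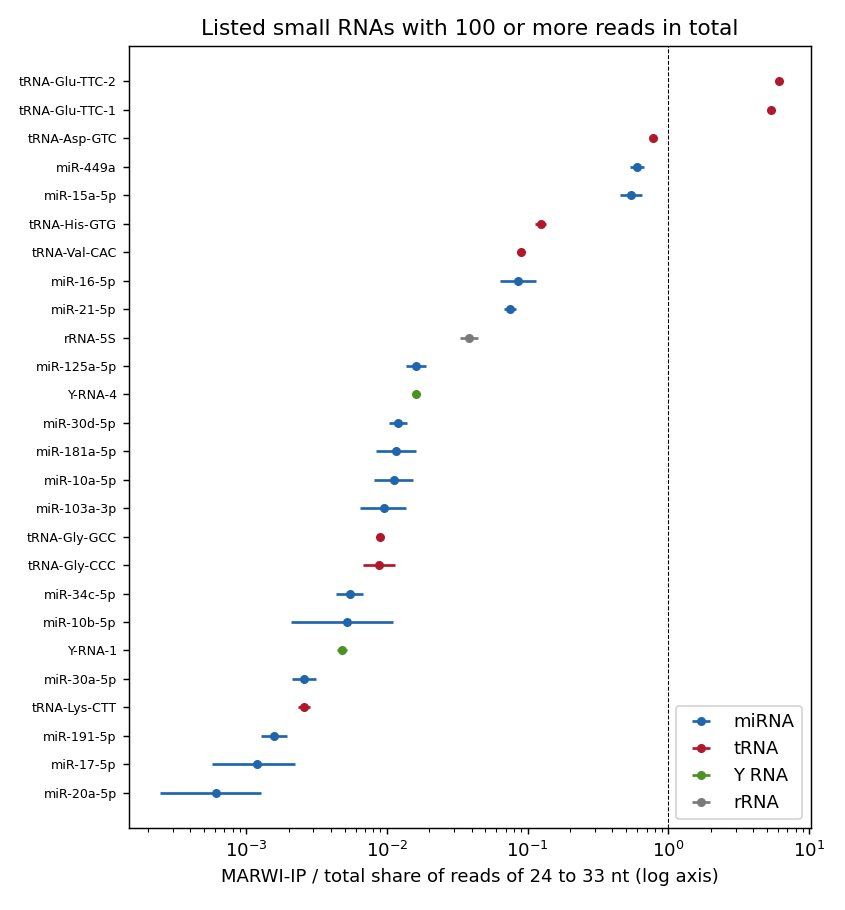
Share of reads in MARWI-IP over that in total small RNA, between 24 and 33 nt on a log axis, for listed miRNAs, tRNA 5′ fragments, Y RNAs and rRNA with 100 or more total reads and at least 1 MARWI-IP read; bars are exact 95% intervals. The tRNA-Glu-TTC fragments lie above 1, at 5.32 and 6.09, and all others drawn lie below, with 1 listed tRNA fragment not used here and not drawn.

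The libraries were also compared sequence by sequence. By reads, the RNAs recovered with MARWI were largely those seen in testis small RNA as a whole. The series held no control immunoprecipitation, so RNA bound by MARWI cannot be told from background. Of piRNA-length MARWI-IP reads, 90.4% had a sequence also present in the total library, and 88.1% of piRNA-length total reads had one present in MARWI-IP. These reads came from 971903 shared sequences, which were 15.6% of the distinct piRNA-length sequences of MARWI-IP. Abundance ranked only in part alike. Across the 103076 shared sequences with 100 or more reads in the sum of both, Spearman's rho was 0.488, where sequences are not independent replicates. The sum weighs the deeper MARWI-IP library more, and counting error in the total library was not taken out. This rho therefore does not measure a difference in ranking alone.

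The most abundant piRNA-length sequence of MARWI-IP was the 29-nt tRNA-Glu-TTC fragment TCCCACATGGTCTAGCGGTTAGGATTCCT, with 2177351 reads (1.98%). TTAGATTGTAAAAATGTGTGCACAACCATG, which matches no listed RNA, had 1072903 MARWI-IP reads (0.974%) and 77470 total reads (0.606%) and was among the leading sequences of both libraries. Of the 5 most abundant MARWI-IP sequences 1 is not used here, and the remaining ones were TCCCATATGGTCTAGCGGTTAGGATTCCT with 1012540 reads and TTGATGGTAATTGGAAGAGCATCTTGGGT with 729827 reads, the latter at 9.72 times its total share (9.52 to 9.93). In the total library the leading sequences were 2 forms of the tRNA-Gly-GCC fragment, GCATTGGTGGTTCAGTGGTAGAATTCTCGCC with 174599 reads and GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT with 88058. TCTTCATTGAGTCTGAAGACACTCCAAGA, with 60032 reads, had 0.730 times its total share in MARWI-IP. After it came the 29-nt tRNA-Glu-TTC fragment with 45392 reads. The 10 most abundant sequences held 5.51% of total reads and 7.84% of MARWI-IP reads.

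RNA-seq described which genes the same tissue expressed. Genes of late spermatogenesis were among the highest protein-coding genes, with a median of 105 RPKM for spermatid markers against 0.810 RPKM for spermatogonial ones, and 19 of the 20 piRNA pathway genes with an entry, of 26 listed, were at 1 RPKM or more. Single somatic genes were also high, the Leydig cell gene INSL3 at 404 RPKM among them. The table listed transcripts above 0, from 0.000844 RPKM, of which 10984 (59.8%) were at 1 RPKM or more. Depth is not stated and transcripts at 0 are not listed, so a gene without a named entry is not shown to be unexpressed.

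Of 18 listed spermatid genes, 14 had an entry. All 14 exceeded 1 RPKM, with a median of 105 RPKM, above all 10000 random lists of equal size drawn from 12199 named protein-coding genes. They were led by PRM1, a protamine that packs sperm DNA (7177 RPKM, chromosome 12, 15851601 to 15852121), the transition protein TNP1 (1678 RPKM, chromosome 6), PRM2 (1484 RPKM) and the outer dense fibre gene ODF1 (480 RPKM). The PRM2 entry spanned 15856569 to 15984738 on chromosome 12. Of 15 listed spermatocyte genes, 8 had an entry. Of these 8, 7 exceeded 1 RPKM, and the list median was 29.9 RPKM, at the 99.95th percentile of random lists. The germ-cell lactate dehydrogenase LDHC stood at 114, HORMAD1 at 65.3, SYCP2 at 59.2 and SYCP1, of the synaptonemal complex, at 49.9 RPKM, while SPO11 was at 0.522 RPKM. Of 13 listed spermatogonial genes, 7 had an entry. Of these 7, 2 exceeded 1 RPKM, DMRT1 at 7.60 and PIWIL4 at 1.52 RPKM, with the list median at the 17.1th percentile. GFRA1 was at 0.854, ZBTB16 at 0.810, STRA8 at 0.463, KIT at 0.290 and SALL4 at 0.246 RPKM. PIWIL4 was in both the spermatogonia and the piRNA pathway list.

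Of 20 piRNA pathway genes with an entry, 19 exceeded 1 RPKM. The median was 9.05 RPKM, at the 99.59th percentile of random lists. The highest were GTSF1 at 57.4, MAEL at 43.0, PLD6, the nuclease also called Zucchini, at 38.5, and the helicase DDX4 (Vasa) at 27.0 RPKM. PNLDC1, which trims piRNA 3′ ends, was at 12.8, the transcription factor MYBL1 at 11.2, PIWIL2 at 9.66 and MOV10L1 at 6.45 RPKM, whereas PIWIL3 was at 0.378 RPKM. PIWIL1, TDRKH, TDRD15, RNF17, HENMT1 and BTBD18 had no entry under their names and were not analysed here. Of 10 listed genes of the miRNA and siRNA pathway, 8 had an entry, DROSHA and AGO1 having none, and all 8 exceeded 1 RPKM, with a median of 7.30 RPKM (91.6th percentile) and XPO5 (12.9), DGCR8 (10.7), DICER1 (9.91) and AGO4 (8.96 RPKM) highest. Of 11 listed DNA methylation and silencing genes, 7 had an entry. Of these 7, 6 exceeded 1 RPKM (list median 6.60, 87.6th percentile). MORC2 was at 17.2, MORC1 at 16.7, SETDB1 at 12.0, DNMT1 at 6.60 and DNMT3A at 0.661 RPKM.

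Somatic cells of the testis were also represented. INSL3, a hormone of Leydig cells, stood at 404 RPKM. The other Leydig genes with an entry were HSD17B3 at 21.9, CYP11A1 at 5.63 and STAR at 4.91 RPKM. All 4 with an entry, of 7 listed, thus exceeded 1 RPKM (93.7th percentile). Of 11 listed Sertoli genes, 6 had an entry (50.6th percentile). Of these 6, 4 exceeded 1 RPKM, CLU at 68.0, CLDN11 at 27.7, WT1 at 3.68 and GATA4 at 1.91 RPKM. AMH, the hormone of immature Sertoli cells, was at 0.148 and AMHR2 at 0.0104 RPKM. All 4 peritubular myoid genes with an entry, of 6 listed, exceeded 1 RPKM (69.8th percentile). They were ACTA2 at 19.4, TAGLN at 6.05, DCN at 4.12 and CNN1 at 2.21 RPKM. Of 5 macrophage genes 2 had an entry, CD163 at 2.13 and CD68 at 0.913 RPKM (25.5th percentile), and the 1 endothelial gene with an entry, TEK, was at 0.713 RPKM (30.7th percentile). HBB, the 1 blood gene with an entry of 5 listed, was at 38.1 RPKM (94.4th percentile). None of the 4 epididymal genes with an entry exceeded 1 RPKM. LCN9 was highest at 0.187, followed by SPINT3 at 0.0389, DEFB118 at 0.0195 and CRISP1 at 0.0174 RPKM, with a median at the 0.04th percentile. The reference genes RPLP0 and HPRT1 were at 36.8 and 7.18 RPKM (90.2th percentile). The other 6 of 8 reference genes, ACTB, GAPDH, PPIA, TBP, EEF1A1 and B2M, matched no entry, so the names miss genes that are widely expressed.

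Over all RNA classes, the 10 highest entries were 9 copies of the spliceosomal U2, U4 and U5 RNAs and the snoRNA SNORD46. The highest was a U5 copy at 524709 RPKM (chromosome 10, 7675817 to 7675932), and SNORD46 was at 56860 RPKM. snRNA entries made up 74.7% and snoRNA entries 15.3% of summed RPKM, against 8.75% for protein-coding entries. Among named protein-coding genes, a ranking chosen after the values were seen, the highest were LOC100406067 at 8965 RPKM (chromosome 4), PRM1, LOC100395646 at 1795 RPKM, TNP1, PRM2, LOC100394811 at 1381 RPKM, the entry named D7UTH3_CALJA at 1326 RPKM, PPP1R2 at 949 RPKM, the ribosomal protein gene RPS29 at 945 RPKM and TUBA3C, an alpha-tubulin, at 868 RPKM. Entries with near-identical copies, such as U RNAs, RPS29 and TUBA3C, are uncertain where reads could have been split between copies.

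**Figure D5:**
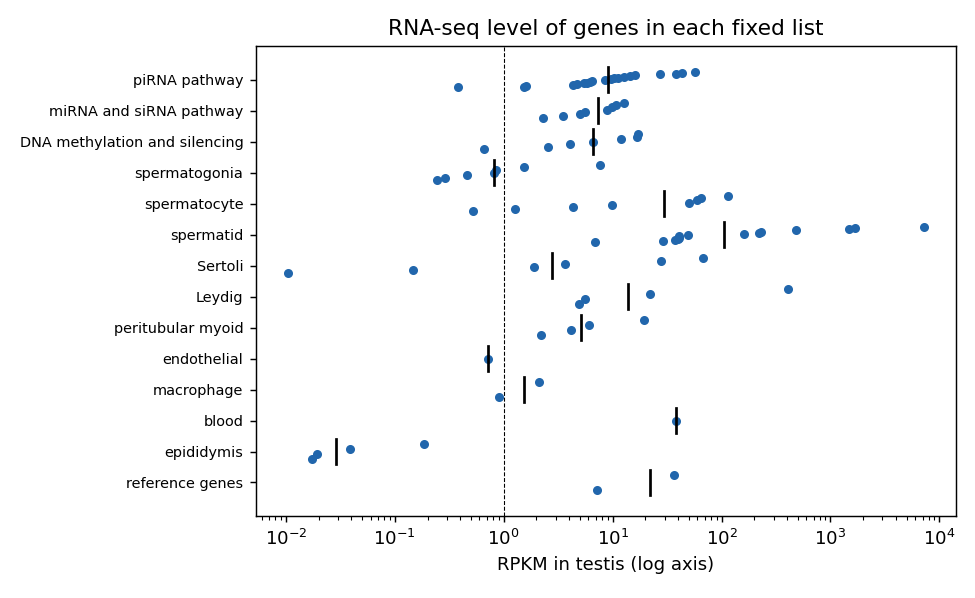
RPKM of the genes with an entry in each of the 14 fixed lists, on a log axis; points are genes, the vertical bar is the list median and the dashed line 1 RPKM. Spermatid genes have a median of 105 RPKM, spermatogonial genes 0.810 RPKM and epididymal genes 0.0292 RPKM.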

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

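The total library held 183122 reads of 34 to 51 nt (1.30% of its reads), longer than any read used in the comparisons and above the 3 reads that a count of 0 allows. They were looked at only after the lengths had been seen, as values without a test of cause. Of these reads, 18314 began with 1 of the 6 listed tRNAs used here and 8533 (4.66%) with a listed Y RNA, and 38.5% began with U. tRNA-Gly-GCC led with 6652 reads, followed by tRNA-Lys-CTT with 6457. The MARWI-IP table holds no reads of this length, so no comparison was made.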

How the results depend on the processing

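The order of the libraries by share of piRNA-length reads and by first U held under each alternative chosen in advance except the count of distinct sequences, and the intervals, which cover counting error alone, were too narrow to hold any alternative value. The log2-scale and neighbour scores, the omission of leading pairs, thinning, the omission from both libraries of either one's 10 most abundant sequences, and the denominators over all lengths were chosen after seeing the data. Values are given as total, then MARWI-IP.

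The planned 10-nt overlap score was -0.323 and -0.0903. It was -0.326 and -0.109 over 24 to 33 nt, -0.309 and -0.323 with each distinct sequence counted once, -0.326 and 0.0323 with sequences read once left out, and -0.311 and -0.175 without the 10 most abundant sequences. Without the leading pair it was -0.323 and -0.256, and without the 5 leading pairs -0.324 and -0.318. On the log2 scale it was -0.00479 and 0.967, and relative to the mean of the neighbouring overlaps 4.28 and 4.74. The sign thus depends on the form of the score, and only the last form, devised after seeing the data, singles out 10 nt. By its construction that form removes the rise of the ratio with overlap length.

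The share of piRNA-length reads (93.8% and 96.7%) was 79.3% and 87.4% with a window of 28 to 31 nt, 90.5% and 90.3% over distinct sequences, 94.5% and 97.0% without sequences read once, and 94.8% and 96.5% without the 10 most abundant. Over all lengths it was 84.9% in total small RNA. A window of 24 to 33 nt gives 100% by construction.

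The share with a first U (84.0% and 89.9%) was 82.4% and 89.6% over 24 to 33 nt, 85.4% and 90.3% over 28 to 31 nt, 85.6% and 90.6% without sequences read once, 86.2% and 89.4% without the 10 most abundant, and 86.6% and 89.9% without the reads of listed miRNAs and of the 6 listed tRNAs used here. Over distinct sequences it was 75.5% and 72.8%, the opposite order, and 76.1% for MARWI-IP thinned to the reads of the total library. A at position 10 (30.6% and 32.2%) was, in the same order, 30.2% and 32.2%, 31.1% and 32.1%, 30.3% and 32.2%, 30.9% and 32.3%, and 31.6% and 32.2%. Over distinct sequences it was 32.3% and 31.5%, again the opposite order, and 31.4% for thinned MARWI-IP, where thinning did not restore it. The cause was not tested.

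The miRNA share of 24 to 33 nt (0.172% and 0.00380%) was 0.00905% and 0.000146% for reads identical to the mature sequence, 0.177% and 0.00395% by the first 16 nt, 0.00471% and 0.00187% over distinct sequences, and 0.199% and 0.00394% without sequences read once. The same settings gave 1.71%, 3.01%, 0.0108% and 3.49% over all lengths of the total library. The share of tRNA fragment reads, with its alternatives, is not given, since 1 listed fragment is not used here.

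The log2 ratio of tRNA-Gly-GCC (-6.81) was -6.86 relative to piRNA-length reads, -6.67 relative to total reads of all lengths, -2.68 without each library's 10 most abundant sequences and -4.48 without those of either. In that order, the less abundant tRNA-Glu-TTC fragment (2.61) had 2.56, 2.75, 0.37 and 2.31. Of 100 values for the 25 small RNAs other than tRNA-Gly-GCC, this fragment among them, 82 lay inside the main interval, 18 outside, and 0 changed sign. Except for the tRNA-Glu-TTC fragments, these settings changed the denominators alone and moved every log2 ratio by the same small amounts. For them no sign could change, and lying inside the interval reflects its width, so the count is not a test of robustness. The MARWI-IP share found in the total library (90.4%) was 89.7% over 24 to 33 nt, 15.6% over distinct sequences, 90.7% without sequences read once and 94.4% by the first 20 nt.

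At 0.1 RPKM the genes detected were 7 for spermatogonia, 2 for macrophages, 1 for endothelium and 1 for epididymis, and at 5 RPKM 1 for spermatogonia, 2 for Sertoli cells, 2 for myoid cells and 0 for macrophages. For all other lists and for the highest entry per gene, counts stayed within 1.5 times.

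No paired analysis was possible because each group was deposited as 1 column, which also ruled out leaving out a replicate and every planned comparison of replicates, with its filters and centring. Pseudocount alternatives were not run, since no log-scale expression value is reported. Cluster, annotation, mismatch, multiple-position, genome-position and gene-by-gene piRNA alternatives were not run for want of a genome.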

Other observations

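All tests in this part were chosen, or their limits written, after the results had been seen, and the chromosome and gene family values were also looked at after the fact.

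Protein-coding RNA-seq entries on the X chromosome had a median of 0.574 RPKM and 40.2% (36.4% to 44.1%) were at 1 RPKM or more, over 637 entries. The 15646 protein-coding entries on numbered autosomes had a median of 1.91 RPKM and 61.8% at 1 RPKM or more. The medians of the 22 autosomes ran from 1.32 to 2.43 RPKM. Among families grouped by symbol, all 14 TEX, 13 SPATA and 5 TEKT genes with an entry were at 1 RPKM or more, with medians of 17.2, 32.8 and 32.4 RPKM, as were 8 of 9 CATSPER genes, led by CATSPERZ at 719 RPKM. Of other families with roles in sperm, 9 of 11 AKAP, 8 of 10 DNAH and 6 of 12 ADAM genes were (ADAM median 0.908 RPKM). Of 12199 named protein-coding genes, 7785 were. All 29 NDUF genes of mitochondrial complex I (median 18.2 RPKM) and all 11 IFT genes of ciliary transport were too. Of 21 olfactory receptor genes none was (median 0.0325 RPKM), and 5 of 19 collagen, 2 of 19 keratin and 1 of 19 HOX genes were.

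The tRNA-Gly-GCC fragment was 112-fold lower in MARWI-IP, a log2 ratio of -6.81 that was -2.68 without the 10 most abundant sequences of each library and -4.48 without those of either. The length filter of the MARWI-IP table could not be tested this way, since the ratio covers only lengths that both libraries hold. Within single lengths of 28 to 32 nt the highest log2 ratio was -3.76, although it was -1.36 at 26 nt and -2.23 at 27 nt. The fragment's share was thus lower in MARWI-IP at each of these lengths. An equal loss of all tRNA fragments over 24 to 33 nt is argued against by fragments listed in advance. Of those starting with G, tRNA-Lys-CTT was at -8.61 and tRNA-His-GTG at -3.01. tRNA-Asp-GTC, which starts with U and whose reads mix forms, was at -0.356. The written condition, a fragment above 1, was met by tRNA-Glu-TTC alone, which was added after seeing the data and is no independent support. The higher tRNA-Glu-TTC value, also of a fragment starting with U, was 2.61. That value is 2.31 without the 10 most abundant sequences of either library and 0.37 when each library loses its own. A selection against a first G may contribute: the fragment's log2 ratio lies below the lower quartile of other sequences starting with G (-5.50) but above their 5th percentile (-9.26), so this stays open. Low ratios were not particular to G. The median log2 ratio was -1.72 for sequences starting with A, -1.51 for C and -1.85 for G, against -0.527 for U. By the labels, the 51-month animal gave a replicate of MARWI-IP and none of the total library. Whether the 1 deposited MARWI-IP column holds both replicates is not stated. An age or animal difference stays open, untested.

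Pairs complementary over 10 nt exceeded those over 9 and 11 nt. The planned score, near 0, is governed by the longest overlaps and does not decide this. Base composition at each position is argued against for the pairs weighted by reads, as the lowest ratio of the 10-nt to the 9-nt or 11-nt value was 5.66 over both libraries. With each distinct sequence counted once, the 10-nt value was 1.18 and 1.38 times that at 9 nt and 0.911 and 0.843 times that at 11 nt in MARWI-IP and total, so no such excess was left. Most of the read-weighted excess may come from the 5 leading pairs: without them the 10-nt ratio was at most 0.254 times its value. Whether a few very abundant sequences account for all of it stays open. Leaving out the 10 most abundant sequences kept the ratio to 9 and 11 nt at 3.80 or more, beyond the limit of 1.5 written for it, but that step removes individual sequences and keeps other forms and partners of the leading 5′ ends, and without the 5 leading pairs the ratio to 11 nt was 1.49 in the total library. This second condition was added after the values were seen. No biological explanation was tested.

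Of 24962 MARWI-IP sequences with 500 or more reads, 166 had at most 1 read in the total library, where a median of 83.9 would be expected at equal shares. They were 0.176% of MARWI-IP reads, and 67 were linked to another of them by 15 nt or more, against a highest count of 14 in 100 random draws. Too few total reads are argued against as far as counting error goes, with 1.55e-21 such sequences expected if reads were independent draws. Amplification adds an error that was not measured. Sequence variants between animals may explain some, since 16.3% differed by 1 base from a total sequence of like abundance, and RNA other than piRNAs stays open, as 68.7% began with U against 93.4% of the other sequences. A difference of the 51-month animal, absent from the total library, stays open, untested.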
